A study of Drosophila melanogaster with 6 samples.

How the data were processed

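Embryos of 2 Drosophila melanogaster stocks were compared, w1118 and a clbn knock-out. Clbn (Caliban, CG11847) is the fly homologue of human NEMF, a component of the ribosome-associated quality control machinery that acts on stalled ribosomes. Per the labels, embryos were collected over 0 to 24 h from flies kept at 25 °C, RNA was purified with a lipid tissue kit, and biotinylated cRNA was hybridised to Affymetrix arrays. There were 3 arrays per genotype, with 1 sample on each. The labels do not say whether the 3 samples of a genotype came from separate collections, so the p-values measure only the spread between these samples, part of which may be technical.

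The values analysed were those of the deposited series table, 18769 probe sets and 183 controls on each of 6 arrays, on a log2 scale. The authors' background correction, summarisation and normalisation are not given in the sources used here. Per the submitters' processing notes the affy software was used, with no version or role. That the values are log2 was read from the deposited values themselves, which ran from 2.84 to 14.52 with array medians between 6.16 and 6.34. The columns were already close to a common scale and were not normalised again. No detection calls were used here, so a low value cannot be told from background. The first quartile lay between 4.27 and 4.35 on every array, and the size of a fold that ends near that level is uncertain. An array gives no count of molecules, and the 3 arrays per genotype limit the precision.

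Genes were named from the platform annotation supplied for the probe sets, which can be old. Of 18769 probe sets that were not Affymetrix controls, 13647 had 1 gene symbol, 402 had several and 4720 were not listed. Of those with 1 symbol, 13544 were matched by gene identifier to the RefSeq gene table of assembly Release 6 plus ISO1 MT, and 0 symbols changed. No gene was named from a probe set with several symbols. Genes that this annotation does not name were not analysed here. The gene table was used only for names, chromosome arm and gene order. The array's genome build is not given in the sources used here, so no coordinates are given. Each of 11982 genes was represented by its probe set of highest mean over all 6 arrays.

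Differences were fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, knock-out minus w1118, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over the 18769 probe sets. A probe set or gene was called changed at an adjusted p below 0.05. Folds are 2 raised to the log2 difference. The means are given ± SD of the 3 arrays, and standard errors (SE) are those of the moderated fit. Gene lists were tested with camera (preset inter-gene correlation 0.01, 2-sided) against all other genes, with adjustment over the 32 lists that had at least 5 measured genes. Of 33 lists fixed, the transposable-element list had no measured gene once matches to ordinary gene symbols were removed, and was not tested. In all, 5 mistaken matches were removed from the lists after the annotation was seen. Camera was repeated with an estimated correlation, and the self-contained test fry was run on the same lists. The 10 nearest measured genes on each side of clbn and the chromosome arms were compared by Fisher's exact test, 2-sided, with exact (Clopper-Pearson) 95% intervals for shares; genes are not independent replicates in these tests. The comparison of chromosomes and arms was chosen after the data were seen. RNA quality was read from the 3′, middle and 5′ Affymetrix control probe sets of actin, eIF-4a and GAPDH and compared by an exact 2-sided permutation test, whose smallest possible p is 0.1. The annotation was prepared in Python 3.11.15 with pandas 2.3.3, and the plots were drawn with matplotlib 3.10.9.

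The genes named follow a rule. It takes clbn, the 12 genes with the largest increase and the 12 with the largest decrease among genes called changed with no overlap between genotypes, up to 4 called members of largest absolute difference per list, or up to 2 of smallest p where none was called, and the called neighbours of clbn. Genes named outside the rule are said to be so. The samples, tests, lists, naming rule and alternatives were fixed before the data were examined, except the chromosome comparisons, the alternatives without chromosome 3, and the tests of embryo age, of knock-out array 1 and of the splits with an estimated correlation.

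The script was tested on simulated data with the real spread, in which 200 of 18769 probe sets were changed in 5 runs of the knock-out against w1118 comparison. It recovered 47.2% of the probe sets changed by 0.5 log2, 89.3% of those changed by 1 and 98.2% of those changed by 2, and 5.08% of its calls were false. The noise was simulated independently between probe sets, so the simulation does not cover the correlation among genes of a list.

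The labels number the replicates 1 to 3 in both genotypes, with no statement of a shared day or batch. The deviations of same-numbered arrays from their genotype means correlated at 0.25, 0.23 and 0.39 for numbers 1, 2 and 3, against −0.33 to 0.09 for arrays of different numbers. All 3 were above the limit of 0.1 set for pairing, and the arrays were taken as paired by number where the text says so. These correlations do not establish a shared collection. The main fit left the pairing out, so its adjusted p-values take no account of it. A fit with the number as a block was an alternative, and it called 978 probe sets changed, against 668 in the main fit. The other alternatives were filters on dim probe sets below the 30th percentile or the median, quantile normalisation, centring on array medians, a trended and robust variance prior, array weights, leaving out each array in turn, the mean of a gene's probe sets, and other windows around clbn.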

Results

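The data were log2 expression values of 18769 probe sets, besides 183 Affymetrix controls, on 6 Affymetrix arrays, 3 from w1118 embryos and 3 from clbn knock-out embryos, collected over 0 to 24 h. All 6 arrays had similar distributions, with medians between 6.16 and 6.34. Pairs of arrays correlated at 0.996 to 0.998 within w1118, 0.994 to 0.997 within the knock-out and 0.986 to 0.995 between genotypes. The first principal component, with 57.7% of the variance, separated the genotypes, and knock-out array 1 lay farthest out on it at 32.4, against 12.4 and 9.56 for the other knock-out arrays and −26.05 to −11.92 for w1118.

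The single comparison of the design set embryos of the clbn knock-out stock against w1118 embryos. The series title links clbn to mitochondrial form, redox state and gut homeostasis. The labels do not give the genetic background of the knock-out stock or any backcross. For genes other than clbn, on any chromosome, an effect of clbn loss therefore cannot be told apart from other differences between the stocks. The same holds for the gene lists. The targeted gene itself was lower in every knock-out array. Clbn (CG11847, on arm 3R) was at 8.19 ± 0.30 in w1118 and 5.28 ± 0.14 in the knock-out (SD, n = 3 each), a log2 difference of −2.91 (SE 0.15, adjusted p = 7.01e-05). The 3 w1118 arrays read 7.86, 8.25 and 8.44, and the 3 knock-out arrays read 5.42, 5.27 and 5.14. The position of this probe set relative to the deleted part of the gene was not analysed here, so the value checks the labels only if the probes lie inside it.

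The largest increase in the knock-out was that of eIF4E3, a paralogue of the cap-binding initiation factor eIF4E, which rose 11.8-fold from 5.43 ± 0.30 to 8.99 ± 0.08 (log2 3.56, SE 0.14, adjusted p = 2e-05). CG13032 rose 11.2-fold and Tektin-C, which encodes a structural protein of ciliary and flagellar microtubules, rose 10.4-fold. The leucokinin receptor gene Lkr rose 7.48-fold, and KaiR1D, which encodes a kainate-type glutamate receptor, rose 5.83-fold. Among the rest, CG5493 rose 4.33-fold, CG44005 3.75-fold, the synaptonemal complex gene corolla 3.73-fold, the glycosyltransferase gene Ugt35A1 3.67-fold, the germline gap junction gene zpg 3.42-fold, CG34437 3.39-fold and hng3 3.36-fold. The w1118 means of CG13032 (4.34), KaiR1D (4.50) and CG34437 (4.28) lay near the first quartile of the arrays. The size of these folds is uncertain, and so is the rank of eIF4E3 above CG13032. The call of zpg was lost without w1118 array 1 (adjusted p = 0.0775), without w1118 array 3 (0.0592) and without knock-out array 2 (0.0562), within a range of 0.00216 to 0.0775 over its alternatives.

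The decreases were larger than the increases at the top of the list. VhaM9.7-c, which encodes an accessory subunit of the vacuolar proton pump, fell 56.7-fold from 10.35 ± 0.01 to 4.52 ± 0.56 (log2 −5.83, SE 0.24, adjusted p = 2.09e-05). The drosomycin-like peptide gene Drsl5 fell 40.7-fold from 11.61 ± 0.17 to 6.27 ± 0.59, and the cyclin-dependent kinase gene Eip63E fell 32.4-fold from 11.12 ± 0.10 to 6.11 ± 0.25. CG11893 fell 10.2-fold, CG42755 9.21-fold and Ppcs, which encodes an enzyme of coenzyme A synthesis, 8.26-fold. The other probe set of Ppcs was lower too but was not called. Smaller decreases were those of CG5402 (7.6-fold), CG40298 (7.4-fold), CG6738 (7.19-fold), the lysozyme gene LysX (5.34-fold) and the heterochromatin protein gene HP1e (4.94-fold). The probe sets of Eip63E and CG42755 carry the suffix that Affymetrix gives to sets shared by several transcripts. Several of the lower values lay near the first quartile of the arrays, where the size of a fold is uncertain.

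**Figure D1:**
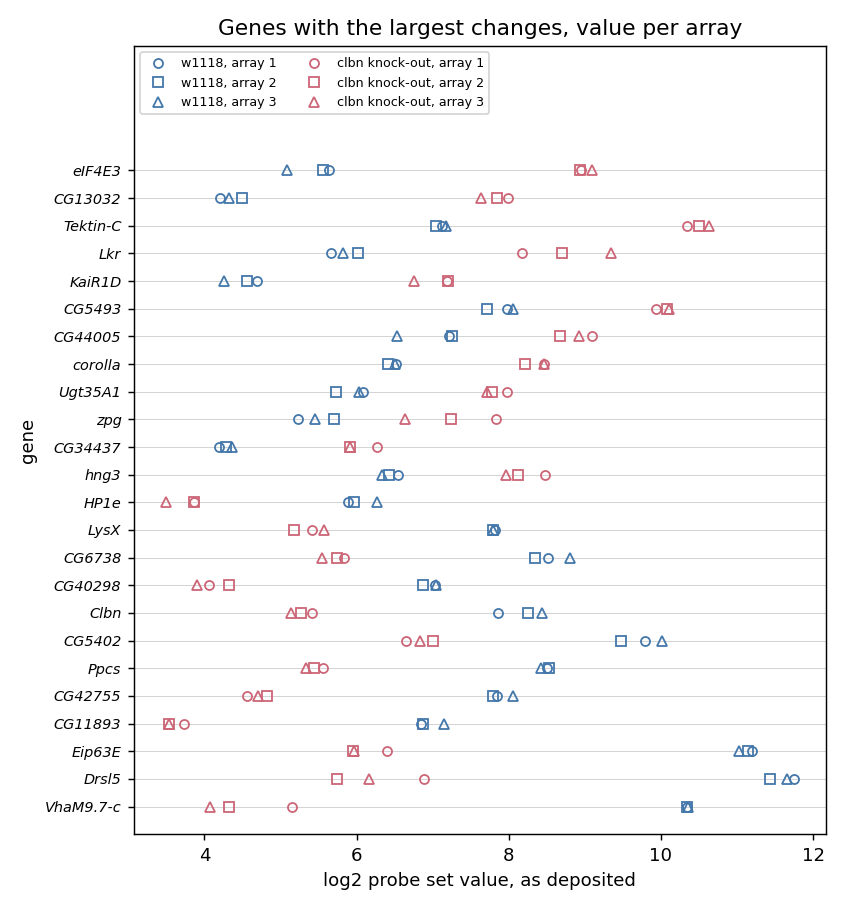
Deposited log2 value (horizontal axis) of each of the 24 genes with the largest changes (vertical axis), with 1 symbol per array; blue symbols are w1118, red symbols the clbn knock-out, and shapes mark the replicate number. For each gene the 3 arrays of one genotype lie apart from the 3 of the other, as the rule that chose these genes requires; VhaM9.7-c goes from 10.35 to 4.52 and eIF4E3 from 5.43 to 8.99.

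Across the array, 668 of 18769 probe sets (3.56%) were called changed, 279 higher and 389 lower in the knock-out, and 133 of them differed at least 2-fold, 50 higher and 83 lower. With the replicate number as a block the lower count was 591. For all 668 the arrays of the 2 genotypes did not overlap; this held for 24.9% of all probe sets, against 10% by chance. At the level of genes, 225 were higher and 315 lower out of 11982. The count of changed probe sets was 190 without w1118 array 1, 256 without w1118 array 3, 357 without knock-out array 2 and 344 without knock-out array 3, and 1539 with array weights.

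The changed genes were unevenly distributed over the chromosomes. On chromosome 3, which carries clbn, 376 of 5318 genes other than clbn were called changed (7.07%), against 153 of 6507 on X and 2 (2.35%; odds ratio 3.16, 95% interval 2.60 to 3.85, Fisher's exact p = 2.71e-35). Both arms contributed, with 181 of 2344 genes on 3L and 195 of 2974 on 3R. Of genes changed at least 2-fold, 84 were on chromosome 3 and 14 on X and 2 (odds ratio 7.44, 95% interval 4.19 to 14.2, Fisher's exact p = 5.71e-17). Of the 24 genes with the largest changes, Clbn included, 21 lie on chromosome 3; the exceptions are CG5493 on 2R, corolla on X and CG42755, which was not placed. The odds ratio was 7.19 without w1118 array 1 and 5.39 without w1118 array 3.

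Whether genes next to clbn were called more often than others depended on the setting. Of the 10 nearest measured genes on each side, 2 were called, against 537 of 11961 other genes (4.49%, Fisher's exact p = 0.226). The other genes are those of all chromosomes, so the p-values here mix the excess on chromosome 3 with any local one. Among the 200 nearest genes 14 were called (7%), against 7.07% of the chromosome 3 genes farther away. Saysd1 rose by 0.35 log2 (adjusted p = 0.0445), a call lost with the replicate block (0.0564, range over its alternatives 0.0107 to 0.183), and Alg9, a glycosyltransferase gene of the N-glycan pathway, had a log2 difference of −0.64 (adjusted p = 0.0407), a call lost with centring on array medians (0.0716, range 0.00642 to 0.158). The number of called neighbours was 6 with array weights (Fisher's exact p = 0.0118) and 4 with median centring (0.014), but 0 among the 5 nearest on each side. It was 3 with quantile normalisation, with the replicate block and without knock-out array 1 (Fisher's exact p = 0.0579, 0.134 and 0.039). It was 0 without w1118 array 1 or knock-out array 2, and 1 without w1118 array 2 or w1118 array 3, and Fisher's exact p lay between 0.0118 and 1 over the alternatives.

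**Figure D2:**
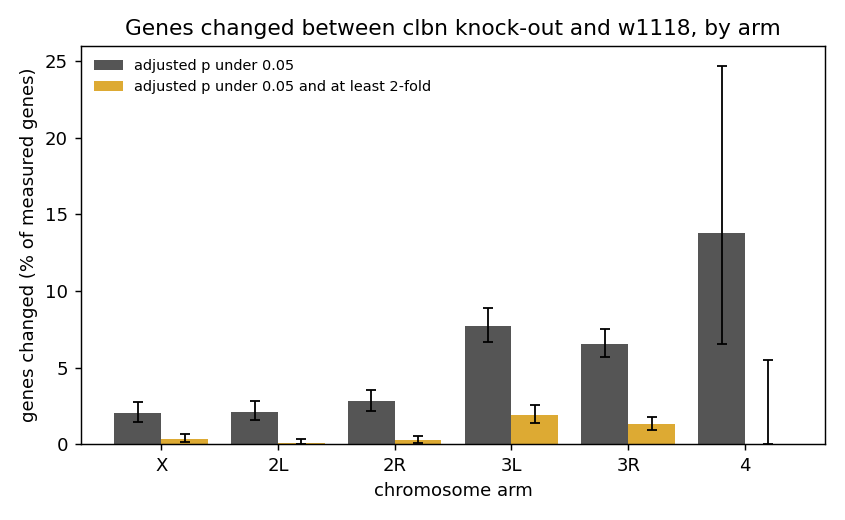
Percentage of measured genes called changed on each chromosome arm (horizontal axis), clbn left out; grey bars count all called genes, yellow bars those changed at least 2-fold, and error bars are exact 95% intervals that treat genes as independent. The grey bars stand at 7.72% on 3L and 6.56% on 3R, against 2.03% on X, 2.13% on 2L and 2.8% on 2R; chromosome 4 has 65 genes and a wide interval of 6.53% to 24.7%.

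By camera with the preset correlation, the lists of cuticle, muscle, neuronal and midgut genes were lower in the knock-out. All 4 lost that call with an estimated correlation (adjusted p = 0.984 each, a value that all 32 lists shared). Camera did not call the lists of other differentiated tissues, with medians of 0.05 for glia (camera adjusted p = 0.935), 0.03 for fat body (0.973), −0.09 for trachea and salivary gland (0.672) and −0.03 for haemocytes (0.362). In the cuticle and chitin list, 28 of 117 fell and 0 rose, with a median log2 difference of −0.32 and a camera adjusted p of 1.41e-17 (adjusted p = 0.984 with an estimated correlation). Adjusted over the list alone, 51 were lower and 2 higher. The cuticle protein genes Cpr67Fa1, Cpr100A, TwdlQ and Cpr65Av fell 4.03-fold, 3.37-fold, 2.56-fold and 2.55-fold. The 2 higher over the list alone, named after their values were seen, were Cpr67Fa2 (log2 0.85) and Cpr78E (0.25). In the body wall and visceral muscle list, 5 of 18 genes fell (median log2 −0.45, camera adjusted p = 2.53e-09, adjusted p = 0.984 with an estimated correlation), 14 when adjusted over the list alone. They were the actin gene Act87E (1.8-fold), the titin-like sls (1.64-fold), paramyosin, Prm (1.53-fold), the myosin light chain Mlc2 (1.51-fold) and, named after its value was seen, Mlp60A (log2 −0.36). The other probe sets of sls and Prm were lower too but were not called.

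The neuronal and midgut lists were also lower by camera with the preset correlation, with fewer single genes called. Of 22 neuronal genes, 21 had values below 0 (median log2 −0.30, camera adjusted p = 0.000181, adjusted p = 0.984 with an estimated correlation), and nrv3, which encodes a sodium pump subunit, was the single gene called, also over the list alone (log2 −0.52, adjusted p = 0.0463). Of 38 midgut and digestive enzyme genes, 3 fell (median log2 −0.19, camera adjusted p = 0.000209, adjusted p = 0.984 with an estimated correlation): LysX, the sterol-binding protein gene Npc2e (2.45-fold) and the trypsin gene lambdaTry (1.61-fold). Adjusted over the list alone, Jon44E was lower too (log2 −0.42), and yip7 (log2 0.62) and Jon65Aiii (0.50) were higher; these 3 were named after their values were seen. The mean of the midgut list overlapped between genotypes, at −0.10 in w1118 array 2 and −0.02 in knock-out array 3, as deviations from the mean of all arrays, but within each of the 3 numbered pairs it was lower in the knock-out. The means of the cuticle, muscle and neuronal lists did not overlap. Knock-out array 1, which had the lowest means of these 3 lists, also had the largest difference between 3′ and 5′ control probe sets, 1.24 log2 against at most 0.779 in the other arrays. Without it the median of the neuronal list was −0.13 (camera adjusted p = 0.0155, and 0.95 with an estimated correlation).

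By camera with the preset correlation, the list of p53 and DNA damage response genes was higher in the knock-out. Of its 18 genes, 2 rose and 17 had values above 0 (median log2 0.18, camera adjusted p = 0.00944, adjusted p = 0.984 with an estimated correlation), and 6 were higher when adjusted over the list alone. Ku80, which binds DNA ends in repair, rose 1.64-fold (adjusted p = 0.0266), and Irbp18, which encodes a leucine zipper transcription factor, rose 1.35-fold (adjusted p = 0.0234). The gene p53 itself, named outside the rule, had a log2 difference of 0.01 (adjusted p = 0.966). Of the 26 names in the list, 7 matched no measured gene (rpr, hid, W, Xrp1, Drice, Diap1 and spn-A), so the result does not cover those. The list's call was lost with the stricter filter on dim probe sets (adjusted p = 0.074) and without the genes of chromosome 3 (0.287, chosen after seeing the data), where the 8 genes left had a median of 0.18, as the whole list had, within a range of 0.000209 to 0.287 among the alternatives that kept the preset correlation.

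With an estimated correlation in place of the preset one, camera called 0 of 32 lists, with 0 at an unadjusted p under 0.05. Its unadjusted p was 0.0762 for muscle, 0.0793 for cuticle, 0.165 for p53 and DNA damage, 0.239 for neurons and 0.248 for midgut. The adjusted 0.984 was shared by all 32 lists and does not rank them. The directional fry test called 0 of 32 lists, with 3 at an unadjusted p under 0.05. The mixed fry test, which asks for change in either direction, called 16. They were the cuticle, muscle, midgut and DNA damage lists, but not the neuronal one (adjusted p = 0.088), and 12 that camera did not call. The smallest adjusted p-values were those of the chaperone and protease list and the cytosolic ribosomal list (0.00033 each). The other 10 were the redox, oxidative phosphorylation, cytochrome P450, glutathione transferase, ecdysone, autophagy and lysosome, insulin and TOR, haemocyte, glia and other adult tissue lists (0.00255 to 0.0462). By camera with an estimated correlation, which asks for a shift in a single direction and so puts another question, each of the 12 had 0.984. In the alternatives that kept the preset correlation, the adjusted p ranged from 1.99e-22 to 2.2e-10 for cuticle, 1.55e-12 to 2.15e-05 for muscle, 4.25e-06 to 0.0155 for neurons and 2.42e-07 to 0.024 for midgut.

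**Figure D3:**
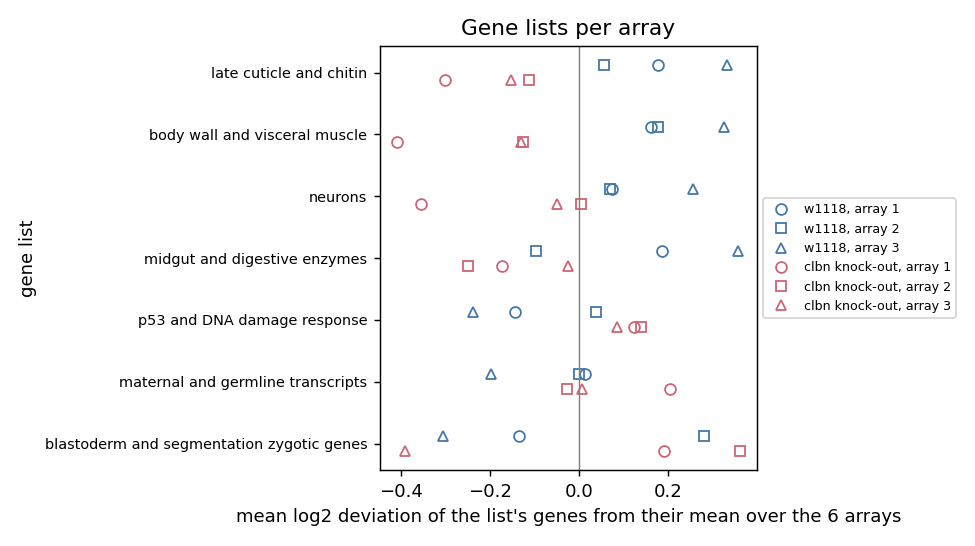
Mean log2 deviation of each list's genes from their mean over the 6 arrays (horizontal axis) for the 5 lists called and for the maternal and blastoderm lists, with 1 symbol per array; blue symbols are w1118, red symbols the clbn knock-out, and shapes mark the replicate number. The cuticle means lie between 0.06 and 0.33 in w1118 and between −0.30 and −0.11 in the knock-out, while the blastoderm means go from −0.31 to 0.28 in w1118 and from −0.39 to 0.36 in the knock-out.

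Mitochondrial and redox genes, which the series title raises, showed single changes, and camera called none of their lists. The mixed fry test did not call the lists of mitochondrial ribosomal proteins and mitochondrial dynamics. It called the list of mitochondrial and cytosolic chaperones and proteases and the redox and oxidative phosphorylation lists (adjusted p = 0.00033, 0.00255 and 0.0152), whose members went both ways. Camera with an estimated correlation gave these lists an adjusted p of 0.984 each, but it asks for a shift in a single direction, which is another question. Among 73 nuclear genes of oxidative phosphorylation, UQCR-11, a complex III subunit, rose 3.02-fold and ND-13B, a complex I subunit, fell 1.38-fold, also over the list alone. UQCR-11 was low in w1118, at 4.84 ± 0.39, so the size of its fold is uncertain. The call of ND-13B was lost with median centring (adjusted p = 0.11, range over its alternatives 0.00373 to 0.155). The list's median was 0.00 log2 and its mean 0.03, while camera pointed downward (adjusted p = 0.953), or upward with median centring (0.932). None of 17 genes of mitochondrial dynamics and quality control was called by limma, with 1 at an unadjusted p under 0.05, and none of 71 mitochondrial ribosomal protein genes, with 8 at that level. Among the latter mRpS26 had a log2 difference of 0.39 (adjusted p = 0.0544, and 0.0391 with the replicate block, range 0.0128 to 0.202) and mRpL11 one of 0.31 (0.0874). The mitochondrial ribosomal list, with a median of 0.06 (camera adjusted p = 0.22), passed the threshold without knock-out array 2 (adjusted p = 0.0247) and without knock-out array 3 (0.0227), but turned downward without knock-out array 1 (0.912), and its adjusted p ranged from 0.0227 to 0.984 over its alternatives. Its mean was 0.157 in knock-out array 1, the array set apart by its RNA quality controls, and −0.061 to −0.005 in the other 5 arrays, as deviations from the mean of all arrays.

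Of 21 redox defence genes 2 fell, the xanthine dehydrogenase gene ry (1.58-fold) and MsrA, which encodes methionine sulfoxide reductase (1.46-fold). Over the list alone Prx6c was also lower (log2 −0.56) and Gtpx higher (0.51), both named after their values were seen. The median of this list was above 0 at 0.05 and its mean below 0 at −0.05 (camera adjusted p = 0.66). Detoxification genes went both ways. Of 35 glutathione transferase genes, GstD3 and GstD4 rose 1.54-fold each and GstZ1 fell 2.02-fold (camera adjusted p = 0.882), and 6 were higher and 2 lower over the list alone, GstE4 (log2 −0.28, named after its value was seen) with GstZ1. Of 83 cytochrome P450 genes 3 rose and 6 fell (camera adjusted p = 0.322), or 6 and 10 over the list alone. Cyp28a5 rose 1.98-fold, and Cyp6a18, Cyp12d1-d and Cyp4d20 fell 1.87-fold, 1.74-fold and 1.69-fold. The other 2 that rose, named after their values were seen, were Cyp9b1 (log2 0.65) and Cyp313b1 (0.41). The w1118 mean of GstD4 (4.57) and the knock-out mean of Cyp4d20 (4.02) lay near the first quartile of the arrays. The size of these folds is uncertain.

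Genes of translation and ribosome quality control, the process in which the NEMF family acts, were largely not past the threshold as single genes. None of 13 genes of ribosome quality control and rescue was called, with 4 at an unadjusted p under 0.05; the smallest p-values were those of Npl4 (log2 0.23, adjusted p = 0.175) and eRF1 (0.18, adjusted p = 0.191). Among 41 cytosolic ribosomal protein genes, the paralogues RpS5b and RpS19b fell 1.44-fold and 1.33-fold, also over the list alone, with values below those of w1118 in all 3 knock-out arrays. The call of RpS19b was lost with median centring (adjusted p = 0.0941), quantile normalisation (0.083) and the trended variance prior (0.0586), within a range of 0.00546 to 0.144. The list's median was 0.01 and its mean −0.02 (camera adjusted p = 0.677), while the mixed fry test called it (adjusted p = 0.00033, and 0.984 by camera with an estimated correlation).

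Other lists had 1 called member each, which also passed when adjusted over the list alone. The ecdysone synthesis enzyme gene spok fell 1.77-fold among 19 ecdysone genes (camera adjusted p = 0.66). Over that list alone ftz-f1 (log2 −0.62) was also lower, and ImpE1 (0.80), ImpE2 (0.72) and Hr3 (0.60), named after their values were seen, were higher. Mitf, which encodes a regulator of lysosomal genes, fell 1.3-fold among 28 autophagy and lysosome genes (camera adjusted p = 0.66), a call lost with median centring (adjusted p = 0.119), quantile normalisation (0.0749) and the trended variance prior (0.074), within a range of 0.00993 to 0.157. The troponin gene TpnC4 rose 2.02-fold in the list of other adult tissues (camera adjusted p = 0.935, with a median below 0 and a mean above 0), and the prolyl hydroxylase gene PH4alphaSG2 rose 1.56-fold in the trachea and salivary gland list (0.672). The w1118 mean of TpnC4 (4.50) and the knock-out mean of spok (4.02) lay near the first quartile of the arrays, so the size of their folds is uncertain.

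The remaining lists had no called member. They covered ribosome rescue, mitochondrial ribosomes and mitochondrial dynamics (above), chaperones and proteases, the JNK, JAK/STAT and EGFR pathways, insulin and TOR signalling, secretory stress, antimicrobial peptides, cell cycle, chromatin, maternal and blastoderm transcripts, glia, haemocytes, fat body and adult ovary. Over the whole array 3533 of 18769 probe sets had an unadjusted p under 0.05 in limma. With Col4a1 counted for both fat body and haemocytes, these 18 lists held 347 entries, of which 46 were at that level. Their medians ran from −0.05 to 0.13 and their camera adjusted p from 0.22 to 0.973, and the mixed fry test called 4 of them, chaperones and proteases (adjusted p = 0.00033), insulin and TOR (0.0152), haemocytes (0.0316) and glia (0.0462), each with 0.984 by camera with an estimated correlation. Adjusted over the list alone, 2 genes were higher and 4 lower. These were REPTOR (log2 0.61, adjusted p over all probe sets 0.0546, and 0.0308 with the replicate block, range 0.0043 to 0.187) and S6k (−0.35) in the insulin and TOR list, and Lon (0.23), Hsp26 (−0.45), Hsp27 (−0.38) and Afg3l2 (−0.26) among chaperones and proteases, with Lon and Hsp26 named after their values were seen. The blastoderm gene zen had a log2 difference of −1.09 (adjusted p = 0.0677, and 0.0128 with the replicate block, range 0.0128 to 0.174), and the haemocyte gene atilla one of −0.59 (0.0628, and 0.0328 with the block, range 0.0233 to 0.183). The blastoderm list passed the threshold without knock-out array 3 (camera adjusted p = 0.00962, range 0.00962 to 0.998), but turned downward without w1118 array 3 (0.998) and without knock-out array 2 (0.737). Median, mean and camera direction differed in sign for chaperones, JNK, insulin and TOR, JAK/STAT, glia and antimicrobial peptides.

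Besides the genes of largest change, 32 called list members and neighbours of clbn were named by the rule, and 18 of them lost their call without at least 1 array. The number lost was 18 without w1118 array 1, 12 without w1118 array 2, 15 without w1118 array 3, 5 without knock-out array 1, 12 without knock-out array 2 and 15 without knock-out array 3. The 18 reached their highest adjusted p, mostly without w1118 array 1, at 0.183 for Saysd1, 0.165 for GstD4, 0.158 for Alg9, 0.157 for Mitf, 0.155 for ND-13B and nrv3, 0.144 for RpS19b, 0.133 for GstZ1, 0.12 for Ku80, 0.119 for sls and Prm, 0.109 for Irbp18 and 0.108 for lambdaTry. Without w1118 array 3 it was 0.0865 for Cyp6a18 and 0.0776 for PH4alphaSG2, without knock-out array 2 it was 0.0876 for ry, and without w1118 array 1 it was 0.0629 for RpS5b and 0.0594 for Cyp12d1-d. The 14 called in each setting that tested them were Act87E, Mlc2, Cpr67Fa1, Cpr100A, Cpr65Av, TwdlQ, Npc2e, UQCR-11, MsrA, GstD3, Cyp28a5, Cyp4d20, spok and TpnC4. Both dim filters left out Cyp4d20 and spok, and the stricter one also left out UQCR-11 and TpnC4. Their calls were therefore not tested there.

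The control probe sets for RNA quality set 1 array apart. The mean difference between 3′ and 5′ control probe sets was 0.744 ± 0.031 log2 in w1118 and 0.880 ± 0.316 in the knock-out (SD, n = 3 each; exact permutation p = 0.8, smallest possible 0.1). Knock-out array 1 stood at 1.24, while the other 5 arrays lay between 0.667 and 0.779. Without it the difference between genotypes was −0.045.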

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

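The comparison of chromosomes itself was chosen after the data were seen; its tests without the nearest genes and of second probe sets were set before their own results. Chosen only after the results were seen were the tests of calls spread evenly over the chromosomes, of embryo age, of knock-out array 1, of the lower lists without chromosome 3 and of the splits with an estimated correlation.

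The signal of 1 Affymetrix control probe set that entered no comparison of genes, AFFX-Dm-U43284-1_s_at, was 5.25 log2 higher in the knock-out. It stood at 7.12 ± 0.37 in w1118 and 12.37 ± 0.03 in the knock-out (SD, n = 3 each; limma adjusted p = 2.87e-07 over the 183 controls). What this probe set detects is not given in the sources used here. The 3′ probe sets for 18S ribosomal RNA and GAPDH also passed the threshold, both lower in the knock-out by less than 2-fold.

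Calls were concentrated on chromosome 3, with an odds ratio of 3.16 against X and 2 (95% interval 2.60 to 3.85). This is not the even spread that a loss of clbn acting alike on genes of every chromosome predicts. That prediction was written after the excess was seen, so its result restates the excess and cannot decide the cause. Gene content was not taken into account either: 22 of the 28 called cuticle genes lie on chromosome 3. A candidate explanation is sequence differences over much of chromosome 3 between the stocks, which predicts an excess on both arms and away from clbn. Without the 100 measured genes on either side of clbn the odds ratio was 3.16 (2.60 to 3.86). Each arm had an excess of its own, 3.47 on 3L (2.77 to 4.36) and 2.91 on 3R (2.33 to 3.64). The genes left out held 14 of the 376 calls, so leaving them out could change little. These values show only that the excess was not confined to the genes near clbn or to a single arm. Any other cause acting along the whole chromosome would give the same, so they do not decide on this explanation. Differences under the probes alone, with unchanged transcript levels, stay open: the second probe set of a called chromosome 3 gene went the same way in 67.5% of 40 genes (exact 95% interval 50.9% to 81.4%), but the bound of 50% set for this test was wrong, since genes not called reached 62.7% on chromosome 3 and 64.9% on X and 2. For genes called at least 2-fold it was 90.9% of 11 (58.7% to 99.8%), an interval that holds those shares too. Of these 11 second probe sets 0 were called, and they moved less than the first (medians 0.15 and 1.23 log2). The second probe sets of all 40 also moved less (0.13 and 0.68), with 4 called the same way and 1 the opposite way. Those of the 12 called genes on X and 2 did so too (0.17 and 0.55, with 75% going the same way, 42.8% to 94.5%). An effect of clbn loss that falls mostly on genes of chromosome 3 was not tested. Differences between the stocks on the other chromosomes were not tested either, and the labels give no backcross.

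The cuticle, muscle, neuronal and midgut lists were lower in the knock-out by camera with the preset correlation. The glia, fat body, trachea and haemocyte lists were not called by camera, with medians of −0.09 to 0.05. With the preset correlation, 4 of these 4 lists stayed lower past the threshold without knock-out array 1 and 4 without genes of chromosome 3. With an estimated correlation none was called with all arrays (adjusted p = 0.984) or without array 1 (0.95). Staying called cannot decide on a cause, since 8 of the 10 splits of the arrays called as many lists with the preset correlation. Whether shorter cDNA or degraded RNA in that array, or sequence differences on that chromosome, lowered the lists was therefore not decided. The sizes show only that the shifts were not confined to either. On genes of X, 2 and 4 the means were −0.32 log2 for cuticle, −0.44 for muscle, −0.29 for neurons and −0.28 for midgut. Without array 1 the mean went from −0.38 to −0.32 log2 for cuticle and −0.44 to −0.35 for muscle. It went from −0.30 to −0.29 for midgut and −0.27 to −0.15 for neurons. The medians went from −0.32 to −0.22 for cuticle, −0.45 to −0.36 for muscle, −0.19 to −0.17 for midgut and −0.30 to −0.13 for neurons. Part of the cuticle, muscle and neuronal shifts thus rests on that array. A younger mean age of the knock-out collections is a candidate explanation that stays open. The maternal and blastoderm lists taken as one had a median of 0.13 log2, with 41 of 54 genes above 0 (camera with the preset correlation, p = 0.086). That fit left out the replicate number, and a blocked fit was not run for these lists taken as one. Slower development of knock-out embryos cannot be told apart from a younger age, because the labels give only the window of 0 to 24 h.

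The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 668 changed probe sets, 133 of them at least 2-fold, 376 called genes on chromosome 3 and 2 called neighbours of clbn. The highest other split gave 0 of each by limma, so 1 split gave as many. Each other split mixes the genotypes, so their difference adds to the spread within its groups and makes calls unlikely. With 0 probe sets called, the other counts of 0 follow and are no separate support. At an unadjusted p under 0.05 the real split had 3533 probe sets and 7 neighbours, and the highest of the others 1677 and 4. Among the other splits that part all 3 same-numbered pairs, the highest were 480 and 1. Of the gene lists, 8 of the 10 splits called as many as the 5 of the real one, and the highest other called 15. With the correlation estimated in each split, camera called 0 lists in each of the 10, with 0 at an unadjusted p under 0.05 in the real split and at most 3 in the others. Whether the calls with the preset correlation come from a structure among the arrays, or from a preset of 0.01 below the estimates of 0.26 for cuticle, 0.44 for muscle and 0.51 for neurons, was not separated. With the arrays taken as paired by number, the highest of the 4 splits that part all 3 pairs, other than the real one, called 10 lists. The other 6 splits part 1 pair.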

How the results depend on the processing

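Clbn itself was lower past the threshold in all 13 alternatives run, with log2 differences of −3.07 to −2.75. The other 23 genes of largest change gave 292 values over 13 settings, of which 3 lost the call, all of zpg, and 0 changed direction. The stricter dim filter left out CG11893, CG13032, CG34437, CG40298, CG42755, HP1e and KaiR1D, so these genes gave no value in that setting. The count of probe sets changed at least 2-fold, 133 in the main fit, stayed within 1.5 times in each alternative (93 to 164). Not all of the 133 were called each time, with 111 shared with array weights and 93 with the stricter dim filter. The chromosome 3 odds ratio ran from 2.21 to 7.19, past the threshold throughout. Its alternatives and those without chromosome 3 were chosen after seeing the data. Values near the first quartile of the arrays limit the size of a fold, and no background level was used here. A pseudocount was not run, since the values were already log2, and setting the stage lists beside the others involved no fit.

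The count of changed probe sets was 1539 with array weights (707 higher, 832 lower). It was 190 to 607 without 1 array (82 to 256 higher, 108 to 351 lower), where fewer samples entered. Among 7467 probe sets of single genes on X, 2 and 4, adjusted over those alone, it was 93. This setting leaves out chromosome 3 and also the probe sets without a single gene, which held 81 of the 668 calls. The 2 omissions were not separated. With the replicate block 978 were changed, 591 of them lower, and 626 of the 668 were shared; Saysd1 lost its call, REPTOR, atilla, mRpS26 and zen gained one, and the antimicrobial list turned (0.918). The neighbours Bili (adjusted p = 0.0304) and lobo (0.0113) and the list members Gtpx (0.0461), Prx6c (0.0395) and Hr3 (0.0111), named after their values were seen, gained one too. Among the genes, lists and comparisons that the text names, the block changed no other call. Called neighbours of clbn numbered 4 with median centring, 6 with array weights, 0 with 5 genes on each side and 0 to 3 without 1 array. The 3′ minus 5′ difference ran from −0.045, without knock-out array 1, to 0.243. The causes of these differences between settings were not tested.

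Of the 32 lists, 0 were called with an estimated correlation, 0 by directional fry and 16 by mixed fry. Adjusted p was 0.984 with an estimated correlation for each of the 5 called lists. By directional fry it was 0.196 for muscle, 0.231 for cuticle, 0.364 for p53 and DNA damage, 0.425 for midgut and 0.587 for neurons, and by mixed fry 0.088 for neurons. The p53 list had 0.074 with the stricter dim filter and 0.287 on genes of X, 2 and 4, where 8 of its 18 genes were left with an undiminished median of 0.18. Otherwise the cause was not tested.

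Lists that were not called turned direction, with these adjusted p-values. With array weights they were antimicrobial (0.744), glutathione transferase (0.709), insulin and TOR (0.901) and JAK/STAT (0.843). With the stricter dim filter they were antimicrobial (0.915) and glutathione transferase (0.962), and with the mean of probe sets antimicrobial (0.883). With median centring they were insulin and TOR (0.971), other adult tissues (0.971) and oxidative phosphorylation (0.932). By directional fry they were glia (0.92), other adult tissues (0.89) and oxidative phosphorylation (0.89). On genes of X, 2 and 4 they were cell cycle (0.947), cytosolic ribosomal proteins (0.947), chaperones (0.668) and other adult tissues (0.824). Lists that turned without 1 array had ranges of 0.74 to 0.94 for antimicrobial, 0.00962 to 0.998 for blastoderm, 0.0633 to 0.886 for cell cycle, 0.445 to 0.973 for EGFR, 0.676 to 0.973 for fat body, 0.701 to 0.965 for glia, 0.705 to 0.94 for glutathione transferase, 0.769 to 0.938 for insulin and TOR, 0.737 to 0.903 for JAK/STAT, 0.0227 to 0.912 for mitochondrial ribosomal, 0.627 to 0.996 for other adult tissues and 0.391 to 0.94 for oxidative phosphorylation. The cause was not tested.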

Other observations

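Some genes of lists that were not called had no overlap between genotypes without passing the adjusted threshold. The JNK pathway genes scaf and puc had log2 differences of −0.64 (limma adjusted p = 0.0807) and −0.24 (0.158), and the glial transcription factor gene repo one of 0.30 (0.125). Of the DNA damage list, 4 genes were higher adjusted over the list alone besides Ku80 and Irbp18. Named after their values were seen, they were Irbp (log2 0.51), which encodes the partner of Ku80 in binding DNA ends, nbs (0.39), Blm (0.36) and tefu (0.32).

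The small chromosome 4 had 9 of 65 genes called, 8 lower and 1 higher (13.8%, odds ratio 6.67 against X and 2, 95% interval 2.85 to 13.9, Fisher's exact p = 2.64e-05), a comparison chosen after the data were seen. Mitf is among its genes. No explanation was tested.

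Blastoderm and segmentation genes followed the replicate number more than the genotype. Their mean deviation from the 6-array mean was 0.28 and 0.36 in the arrays numbered 2, −0.31 and −0.39 in those numbered 3, and −0.13 and 0.19 in those numbered 1, for w1118 and the knock-out in turn.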
